A study of Mus musculus with 6 samples.

How the data were processed

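Polyadenylated RNA of mouse oocytes and early embryos was measured by paired-end sequencing in 6 libraries, each made from 60 oocytes or embryos of ICR-background females aged 21 to 23 days, per the labels. The samples are labelled YAP-null (YAPko in the titles) or wild type. The titles do not say which cells of the females lacked Yap1. Fully grown oocytes at the germinal vesicle (GV) stage, arrested before meiotic maturation, gave 2 YAP-null and 2 wild-type libraries. Embryos at the 4-cell stage gave 1 YAP-null and 1 wild-type library. The labels' source field calls the 4-cell samples GV oocytes, while their titles and stage fields call them 4-cell embryos; the titles were used. The genotype of the fathers is not given in the sources used here.

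The authors deposited a gene table per library whose FPKM column holds mapped fragments normalised to transcript length and to library size, per the file headers. Per the submitters' processing notes, reads came from CASAVA 1.8 and were aligned with TopHat to mm9; the TopHat version, the quantification tool and its annotation release are not given in the sources used here, although the columns have the layout of a Cufflinks gene table. Each table has 23813 lines with a lower and an upper bound for every FPKM value, whose confidence level is not given. For some genes, Bcl2l10 among them, the deposited value lies outside its own bounds, so bounds are printed for Yap1 only. The 1 line with a failed status was left out and 260 symbols listed at several loci were summed, which left 23308 symbols. Positions are in mm9, counted from 1.

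The tables give no read counts, so the number of mapped fragments is unknown. Relative depth was first estimated from the deposited bounds, with wild-type GV library 1 set to 1. It was then refined, near that estimate only, from the spacing of the lowest FPKM values, taken as small whole numbers of fragments. The refined depth was 0.374 in wild-type GV library 2 and 0.314 and 0.401 in YAP-null GV libraries 1 and 2. It was 0.795 in the YAP-null 4-cell library (0.798 from the bounds alone) and 0.973 in the wild-type 4-cell library. From 31.8% (YAP-null 4-cell library) to 67.7% (wild-type GV library 2) of the low values compared lay on such steps, so these depths are approximate. The median half-width of the deposited bounds over 2771 genes between 10 and 1000 FPKM was 5.39% to 11.4% of the value across libraries. These bounds cover counting and assignment error in 1 library, not the spread between animals.

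Values were used as deposited and compared as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the libraries compared were kept. The GV groups were compared with limma 3.58.1 (limma-trend, R 4.3.3) on 4 libraries without a replicate block, since the labels do not say that a replicate number marks a shared animal or day. The test was two-sided at a Benjamini-Hochberg adjusted p of 0.05. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333. On simulated data in these libraries the GV test recovered 0%, 0%, 52% and 80% of planted log2 changes of 1, 2, 4 and 6, with 0 false calls. The 4-cell stage has 1 library per genotype and was not tested, since the spread between embryo samples is unknown: genes were counted by a 2-fold size rule, and gene groups were placed among 10000 random lists of the same size, matched on mean 4-cell expression in 20 bins. A percentile outside 2.5 to 97.5 was counted. Such a percentile compares genes within a single pair of libraries and says nothing of the spread between embryo samples. In simulated lists of genes drawn at random, 1 of 40 without a shift and 34 of 40 with a shift of 0.5 fell outside.

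Stage sets were defined on the mean of both genotypes, so that the choice favours neither: the zygotic set holds genes at least 4-fold higher in the mean of both 4-cell libraries than in the mean of the 4 GV libraries, and the maternal decay set those at least 4-fold lower. Before the data were examined, 24 gene lists were fixed. They covered Hippo-YAP components, YAP-TEAD targets known from somatic cells, oocyte and maternal-effect genes, mRNA decay, 2-cell stage genes, pluripotency, trophectoderm, growth and metabolism machinery, chromatin, p53, RNA quality, other ovarian and blood cells, sperm transcripts and Y-linked genes. For the GV stage the lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, over the 22 lists with at least 3 measured members. The list of mitochondrially encoded genes had 0 symbols in the tables. Sperm transcripts had under 3 measured members at the 4-cell stage, and Y-linked genes under 3 in GV oocytes.

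Genes were named by a rule fixed in advance. It took Yap1, then up to 12 genes per direction with complete separation and at least a 2-fold change in GV oocytes (those with the smallest p where no gene passed). It took the 12 largest 4-cell differences per direction at 10 FPKM or more, the 10 largest stage differences per direction, up to 2 members per list and direction, and Rpl13 and Rrm2. Predicted gene models were counted and not named. Genes named outside that rule are pointed out. Alternatives planned before the data were examined changed the pseudocount (0.1 and 5 FPKM), the filter (none, and 5 FPKM), the scaling (median ratio, the same sum for each library, quantile normalization), the limma settings, a replicate block, the stage-set definitions and the fold, and left out each GV library in turn. Chosen after seeing the data were the block with median-ratio scaling, the removal of symbols at several loci or of genes listed at 0, the removal of the trend along the GV replicate split, a rule on non-overlapping bounds, a grouping by replicate number, the gene lists without Yap1 and the estimated correlation without each GV library. Transcript lengths for 1 of the tests in the closing part came from a newer mouse annotation, matched by symbol for 94.2% of the genes tested. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.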

Results

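RNA sequencing profiles were compared between YAP-null and wild-type mouse oocytes and embryos, with 2 libraries per genotype at the GV stage and 1 per genotype at the 4-cell stage. YAP is the transcriptional coactivator at the end of the Hippo pathway. The series asks, by its title, whether YAP stored in the oocyte switches on the genes of the early embryo. In each library 9984 to 10823 genes reached 1 FPKM. The sum of FPKM was 462324 and 362849 in YAP-null GV libraries 1 and 2, 366398 and 370735 in wild-type GV libraries 1 and 2, 385350 in the YAP-null 4-cell library and 441516 in the wild-type 4-cell library. A single small RNA gene, Mir762, named after its values were seen, held 88240 FPKM or 19.1% of the sum in YAP-null GV library 1. Read totals are unknown.

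Yap1 transcript was low in the libraries labelled YAP-null at both stages. In GV oocytes Yap1 (chromosome 9, 7932001 to 8004596) averaged 10.4 ± 0.537 FPKM in YAP-null and 200.8 ± 66.8 FPKM in wild-type libraries (SD, n = 2 each), so the YAP-null level was 5.19% of wild type. The share was 4.35% between the libraries numbered 1 and 6.54% between those numbered 2. At the 4-cell stage Yap1 was at 33.3 FPKM (deposited bounds 30.9 to 35.8) in the YAP-null library and at 89.7 FPKM (86.0 to 94.0) in the wild-type library, which is 37.2% of wild type. The YAP-null 4-cell library therefore held more Yap1 transcript than either YAP-null GV library. The difference was -4.10 ± 0.387 (SE) on the log2 scale in GV oocytes, -4.40 and -3.81 within the libraries numbered 1 and 2, and -1.40 at the 4-cell stage. In the limma test of GV oocytes the unadjusted p was 0.00017 and the adjusted p over all genes was 1.00, so Yap1 did not pass. Without any 1 of the 4 libraries it passed in limma, at an adjusted p of 0.0126 and 0.00786 without YAP-null library 1 or 2, 0.000129 without wild-type library 2 and a value between these without wild-type library 1.

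**Figure D1:**
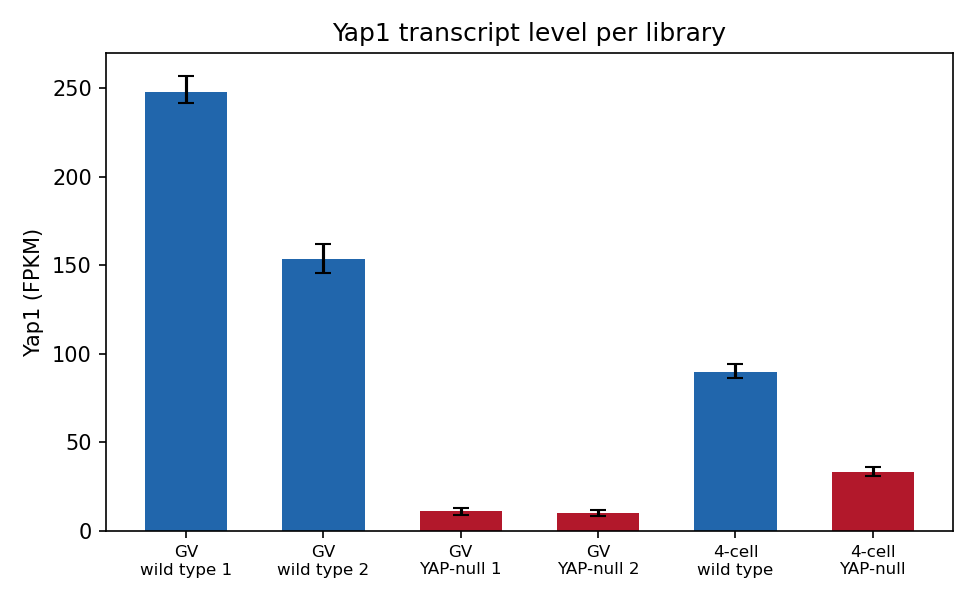
Yap1 FPKM in each of the 6 libraries, wild type in blue and YAP-null in red, with the deposited bounds as bars. The YAP-null libraries sit at 10.04 to 33.3 FPKM and the wild-type libraries at 89.7 to 248.05 FPKM.

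The first comparison asked which transcripts differ in the oocyte itself between libraries labelled YAP-null and wild type. Apart from Yap1, few genes had large differences that repeated in both libraries of each genotype. Stk32a, a serine/threonine kinase gene, was at 6.55 and 8.78 FPKM in YAP-null and at 0.0572 and 0.381 FPKM in wild-type oocytes, a log2 difference of 2.83 ± 0.379 (SE). Pxdn, which encodes the extracellular matrix enzyme peroxidasin, was at 0 and 0.160 FPKM in YAP-null and at 6.17 and 2.55 FPKM in wild-type oocytes, a log2 difference of -2.23 ± 0.467. Mfhas1, Akr1c21 and Defb41 were higher in both YAP-null libraries than in both wild-type libraries, by 1.44, 1.11 and 1.15 on the log2 scale. Tlcd2 and the ribosomal protein gene Rpl26 were also higher in both, but unevenly, by 3.48 and 0.70 (Tlcd2) and by 0.56 and 2.38 (Rpl26) within the libraries numbered 1 and 2. The log2 differences of the lower genes were -1.42 for Gsto2, -1.64 for Dynlt1c, -1.29 for Olfr1349, -1.25 for Lemd1, -1.28 for the ribosome biogenesis gene Rrs1, -1.28 for the steroid enzyme gene Hsd3b1, -1.13 for Tmem216, -1.07 for Prl8a2 and -1.14 for Fam173b, and Pla2g4e was lower by value at -2.44 and -0.78 within the numbers. Most of these genes were under 10 FPKM in every GV library, and none of them passed this test. Genes that mark the growing oocyte differed little: Bcl2l10 averaged 1617 ± 552 FPKM in YAP-null and 1570 ± 372 FPKM in wild-type libraries, and Zar1 919 ± 239 and 1025 ± 226 FPKM (SD, n = 2).

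Of 10462 genes tested with limma, 0 passed an adjusted p of 0.05 and 22 had an unadjusted p under 0.05. With the replicate block 2 genes passed, Yap1 and Stk32a. The libraries split by replicate number more than by genotype. Between the replicates of 1 genotype, 2807 genes (YAP-null) and 2438 genes (wild type) lay at least 2-fold apart, while between genotypes there were 163 such genes within the libraries numbered 1 (63 higher and 100 lower in YAP-null) and 163 within those numbered 2 (69 higher and 94 lower), each over the genes with a mean of at least 1 FPKM in the pair. Over the 10462 tested genes, 60 and 66 were at least 2-fold higher and 113 and 92 lower within the numbers 1 and 2. Of these, 20 genes were at least 2-fold apart in the same direction in both, 6 higher in YAP-null oocytes (0.379 expected if the genotype differences within the numbers were unrelated) and 14 lower (0.994 expected). Both expectations treat all genes as equally likely to be 2-fold apart. Genes at low FPKM can vary more in both pairs, so the expected numbers may be too low. Of the 20 genes, those higher include Stk32a, Mfhas1, Akr1c21 and Defb41. Those lower include Yap1, Pxdn, Gsto2, Hsd3b1, Rrs1, Dynlt1c and the splicing factor gene Cdc5l, which was at 0.232 and 1.00 FPKM in YAP-null and at 1.602 and 16.7 FPKM in wild-type oocytes. Across the tested genes the differences within the 2 numbers showed almost no correlation (r = 0.0136, rho = -0.0479, across genes, which are not independent replicates). Leaving out YAP-null library 1 or 2 gave 2 and 3 genes past the threshold, and leaving out wild-type library 1 or 2 gave 7 and 5, in fits where the lone library is assumed to vary like the others.

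**Figure D2:**
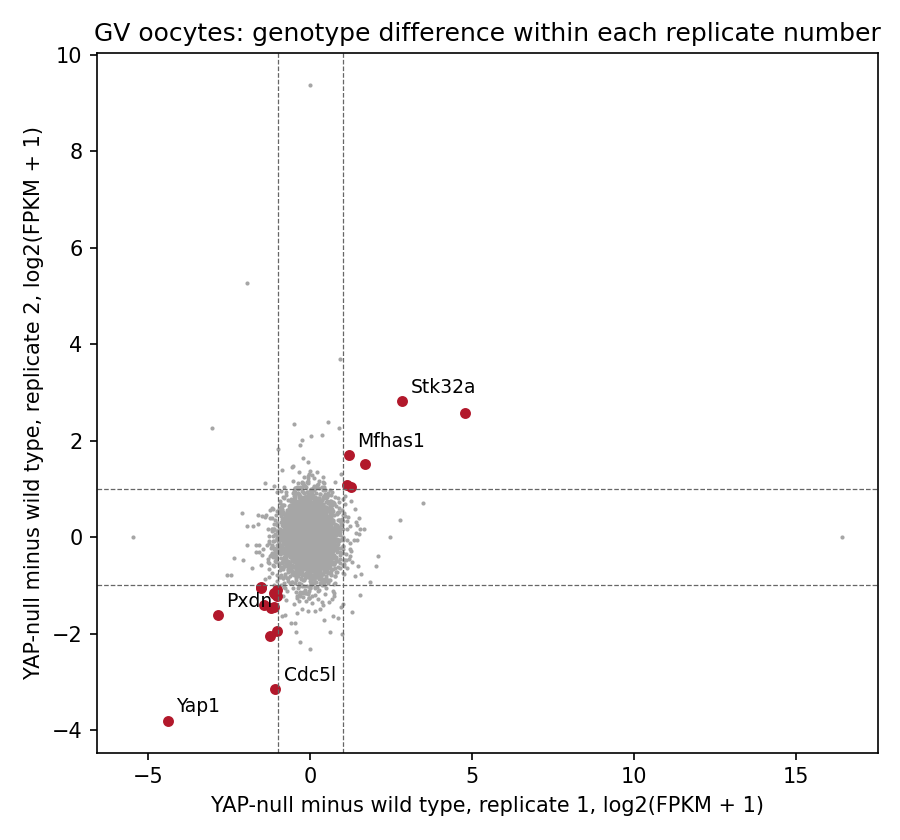
Difference of log2(FPKM + 1) between YAP-null and wild-type GV oocytes, for the libraries numbered 1 on the horizontal axis and those numbered 2 on the vertical axis, 1 point per gene, with dashed lines at 2-fold. The 20 genes at least 2-fold apart in the same direction in both are red, and Yap1 lies at -4.40 and -3.81.

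The fixed gene lists differed little in value in GV oocytes, with medians between -0.27 and 0.14 on the log2 scale. The 33 measured oocyte and maternal-effect genes had a median difference of -0.03 (-0.05 and -0.08 within the libraries numbered 1 and 2), with Ooep at -0.24 and Kit at 0.18. The 18 Hippo-YAP components had a median of 0.00 (-0.17 and -0.05 within the numbers), and 1 of them, Yap1, changed when p was adjusted over the list alone. Wwtr1, the gene of the YAP homologue TAZ, differed by 0.30. The 5 measured YAP-TEAD targets had a median of 0.10 (0.04 and -0.08), with Gadd45b at 0.30 and Birc5 at -0.15. Granulosa and cumulus cell genes, which mark cells that surround the oocyte, had a median of -0.14 over 12 genes, with Hsd3b1 at -1.28 and Inha at -0.77, and with Kitl at 0.54 and Cyp19a1 at 0.33 in the other direction. Glycolysis genes had a median of -0.07, with Eno1 at -1.13. Within the numbers 1 and 2 the values were uneven for Inha (-0.31 and -1.22), Kitl (0.07 and 1.01) and Eno1 (-0.47 and -1.78). The 3 genes of ovarian stroma and blood had a median of -0.27. Camera passed 0 of 22 lists, with a smallest adjusted p of 0.160 and 3 lists at an unadjusted p under 0.05. The smallest adjusted p was 0.970 with an estimated correlation and 0.993 with fry. With so few libraries, camera at an estimated correlation could hardly pass any list. Without 1 library, 5 and 6 lists (YAP-null library 1 or 2 left out) and 5 and 4 lists (wild-type library 1 or 2 left out) passed at the preset correlation, and the ribosomal protein, proteasome, DNA replication and DNA methylation lists changed direction with the library left out. None of these calls stood with an estimated correlation, but that setting, with fewer libraries still, could not have decided on them. With a mean of at least 5 FPKM the Hippo-YAP list, which holds Yap1 itself, passed camera at the preset correlation (adjusted p = 0.0111). It did not pass with an estimated correlation (0.970) or with Yap1 left out (0.822).

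The second comparison asked how 4-cell embryos labelled YAP-null differ from wild-type embryos. At this stage YAP-null is the label of the library, which still held 37.2% of the wild-type Yap1 level, and the genotype of the fathers is not given in the sources used here. The largest named difference in the higher direction was that of the repeated small RNA gene Rn4.5s, summed over 10 loci, at 153 FPKM in the YAP-null library and listed at 0 in the wild-type library and in all GV libraries (log2 difference 7.27, a size set by the pseudocount). The other named genes were transcripts of the oocyte. Bcl2l10, an antiapoptotic gene abundant in oocytes, was at 583 FPKM in the YAP-null and at 14.4 FPKM in the wild-type library, 40.4-fold higher. Zar1, a maternal-effect gene needed for the first cleavages, was at 130.4 and 3.60 FPKM, 36.2-fold higher. Tcl1, Tcl1b3 and Tcl1b4, of a family of AKT coactivators, were higher by 5.19, 4.97 and 5.57 on the log2 scale. The subcortical complex gene Zbed3 was higher by 4.81 (1137 and 39.7 FPKM), the oocyte cap-binding gene Eif4e1b by 4.64, Rfpl4 by 4.63, Rgs2 by 4.81, and the oocyte homeobox genes Obox1 and Obox2 by 4.34 and 4.63.

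The largest differences in the lower direction were of a different kind. Rpl26, Cphx2, Amd1, Plac9a, Hba-a2 and Rnaset2a were at 0.000796 to 0.0940 FPKM in the YAP-null library and at 16.4 to 196.8 FPKM in the wild-type library, and each has a close copy or an overlapping gene model. Summed with that copy, Amd1 was at 196 FPKM in both libraries, Cphx2 at 290 and 261 FPKM and Rnaset2a at 39.9 and 29.5 FPKM (YAP-null first). The sums of Rpl26 (508 and 891 FPKM), Plac9a (29.4 and 70.0 FPKM) and Hba-a2 (25.9 and 52.3 FPKM) stayed lower. Beta-s and Hbb-b2, haemoglobin genes of red blood cells, Nupr1, a stress-response gene, Aqp3, a water channel gene, and Ckmt1, a mitochondrial creatine kinase gene, were listed at 0 in the YAP-null library and at 25.2, 15.9, 16.8, 16.5 and 15.8 FPKM in the wild-type library. Pet117 was at 16.3 FPKM in the wild-type and at 4.19e-34 FPKM in the YAP-null library. Rpl13 was lower by value, at 413.7 and 898.6 FPKM (log2 difference -1.12), and so was Rrm2, a subunit of ribonucleotide reductase, at 66.8 and 135.1 FPKM (-1.01).

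Of 10854 genes, 3007 (27.7%) lay at least 2-fold apart between the 4-cell libraries, 1925 higher and 1082 lower in the YAP-null library (64.0% higher). No test was made, because 1 library per genotype gives no spread between embryo samples and the spread of GV oocytes would have to stand in for it. In GV oocytes 23.3% and 26.9% of genes lay as far apart between replicates of 1 genotype, and 1.62% and 1.54% between genotypes within the numbers 1 and 2. The labels do not say whether the 4-cell libraries were prepared together, so neither range can be chosen as the measure of this count. The count was 1275 with a pseudocount of 5 FPKM, 1723 at a mean of at least 5 FPKM and 696 at 4-fold. The share higher was 53.4% with quantile normalization and 71.1% with each library rescaled to the same sum, which moved the median difference of all genes from 0.05 to 0.26. The 4-cell differences showed almost no correlation with the GV differences (r = 0.00752, rho = 0.0187 across 8915 genes).

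Genes that come up between the oocyte and the 4-cell embryo were slightly lower in the YAP-null 4-cell library. The zygotic set of 2048 genes had a median difference of -0.25 on the log2 scale, with 1368 genes (66.8%) below 0, 245 at least 2-fold lower and 67 at least 2-fold higher. Gata6, a transcription factor gene of the primitive endoderm, was at 5.03 FPKM in the YAP-null and 52.1 FPKM in the wild-type library, Tdgf1, which encodes a Nodal co-receptor, at 6.48 and 41.8 FPKM, Impdh2, of guanine nucleotide synthesis, at 299.6 and 914.7 FPKM. Crxos1, a homeobox gene, was at 232.7 and 600.5 FPKM. Most zygotic genes were present in both libraries: the median stage difference of the set was 3.08 in wild type and 2.87 in YAP-null. In GV oocytes the median genotype difference of the set was 0.00 (0.00 within each replicate number). That value says little. The set is by definition at least 4-fold lower in GV oocytes, and some members, such as Crxos1, were listed at 0 in every GV library. None of the 10000 matched random lists had a median as low (percentile 0, with 95% of random medians from -0.11 to -0.04). The size of the median was sensitive to scaling, -0.44 with median-ratio scaling and -0.04 with each library rescaled to the same sum, against medians of all genes of -0.08 and 0.20. The numbers at least 2-fold apart moved with it, to 390 lower and 41 higher of 2133 genes with median-ratio scaling and to 244 lower and 198 higher of 2500 genes with each library rescaled. The median was -0.39 when the set was defined on wild-type libraries and -0.13 on YAP-null libraries.

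Transcripts lost between the oocyte and the 4-cell embryo were higher in the YAP-null 4-cell library. The maternal decay set of 1720 genes had a median difference of 0.71, with 699 genes (40.6%) at least 2-fold higher and 70 (4.07%) at least 2-fold lower. Mos, the kinase gene that holds the egg in meiotic arrest, was at 22.6 FPKM in the YAP-null and 0.414 FPKM in the wild-type library, Gja4, the connexin gene of the oocyte gap junctions, at 16.4 and 0.697 FPKM, and Oas1e at 46.2 and 1.78 FPKM. Other maternal transcripts were low in both libraries: Plat, which encodes tissue plasminogen activator, was at 9.46 and 2.72 FPKM, Gpr1 at 0.995 and 0.369 FPKM, and Gtsf1, a piRNA pathway gene, at 3.57 and 5.83 FPKM. The set was still far below its oocyte level, with a median stage difference of -2.43 in YAP-null and -3.13 in wild type. In GV oocytes its median genotype difference was 0.00 (0.02 and -0.02 within the libraries numbered 1 and 2). All 10000 matched random lists had a lower median (percentile 100, with 95% of random medians from 0.09 to 0.20). The median was 0.20 for a set defined on YAP-null libraries alone (percentile 98.9) and 1.12 for genes at least 8-fold apart between stages.

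**Figure D3:**
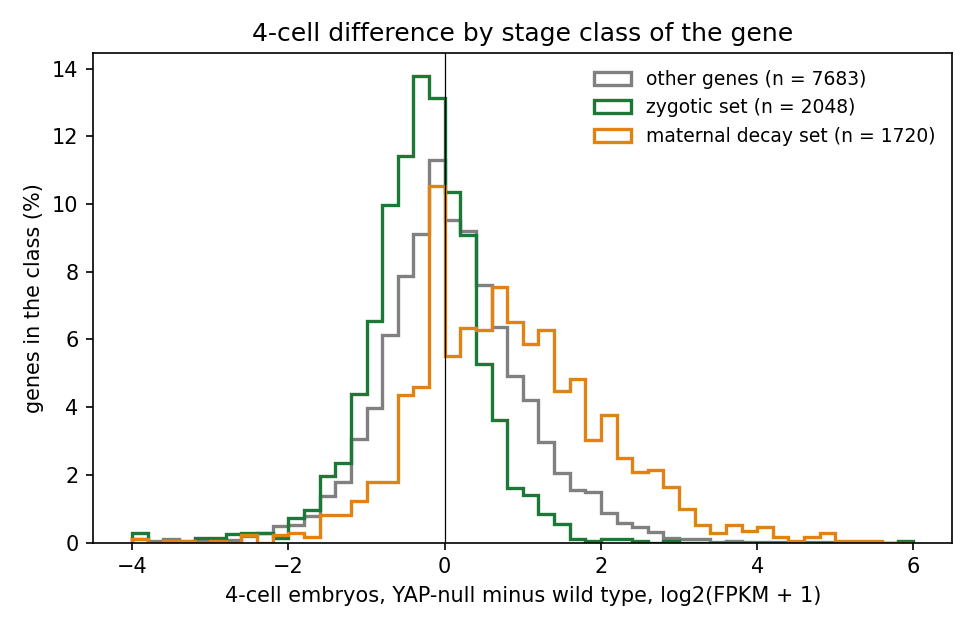
Distribution of the 4-cell difference of log2(FPKM + 1), YAP-null minus wild type, as the percent of genes in each class, for the zygotic set (2048 genes), the maternal decay set (1720 genes) and all other genes. The maternal decay set is shifted to the right (median 0.71) and the zygotic set to the left (median -0.25).

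Among the 22 fixed lists described at the 4-cell stage, 11 had a median outside the 2.5 to 97.5 percentile range of matched random lists. For lists of unrelated genes 1.1 would be expected. Genes of 1 list can vary together, so the excess over that number is no measure of chance. The lists also overlap the stage sets: the oocyte and maternal-effect list had a median stage difference of -5.98 in wild type. The oocyte and maternal-effect list stood furthest apart, with a median difference of 2.75 and 30 of 34 genes at least 2-fold higher. Besides Bcl2l10 and Zar1, Ooep was at 63.2 FPKM in the YAP-null and 2.97 FPKM in the wild-type library and Kit at 16.4 and 4.44 FPKM. The exceptions include Dppa3, which protects the maternal genome from demethylation, at 1440 and 1625 FPKM, and Trim28, at 180.7 and 327.2 FPKM, both higher in 4-cell embryos than in oocytes. The mRNA decay machinery list had a median of 0.29 (percentile 95.3), with 7 of 24 genes at least 2-fold higher, among them Btg4, the adaptor that brings the CCR4-NOT deadenylase to maternal mRNAs, at 440.5 and 30.4 FPKM, and the decapping gene Dcp1a at 83.4 and 9.61 FPKM. The 2-cell stage list had a median of 0.37 (percentile 95.9), with 6 of 32 genes at least 2-fold higher and 2 lower. Replication-dependent histones, whose mRNAs lack a poly(A) tail, had a median of 1.32 over 9 genes (percentile 98.9), which turned to -0.01 over 36 genes with no low-value filter.

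Lists of growth and of early lineage genes lay on the low side. Cytosolic ribosomal protein genes had a median of -0.90, with 34 of 86 at least 2-fold lower and 0 higher. Rpl3 was at 114.6 FPKM in the YAP-null and 551.6 FPKM in the wild-type library. Translation factors had a median of -0.65 (10 of 47 lower, with Eef1g at 74.9 and 232.8 FPKM), oxidative phosphorylation -0.54 (14 of 77 lower and 1 higher, with Ndufs5 at 3.94 and 54.7 FPKM) and proteasome -0.51 (4 of 35 lower). The median was -0.48 for the spliceosome (4 of 42 lower, with Srsf3 at 52.7 and 132.6 FPKM) and -0.46 for DNA replication and nucleotide synthesis (8 of 47 lower and 2 higher, with Pold1, the catalytic subunit gene of polymerase delta, at 1.66 and 9.54 FPKM). Ribosome biogenesis had the same median of -0.46, with the nucleolar gene Npm1 at 738 and 1651 FPKM, but lay inside the range of random lists (percentile 2.76). Pluripotency and preimplantation regulators had a median of -0.78, with 10 of 25 at least 2-fold lower and 0 higher. Gata6 and Tdgf1 were the lowest, and Pou5f1, the gene of OCT4, was at 322 and 207 FPKM. Trophectoderm genes had a median of -0.48 (7 of 15 lower and 2 higher), with Aqp3 and the tight junction gene Cldn4 (2.60 and 28.1 FPKM) lowest. The list of ovarian stroma, blood and immune cells had the lowest median, -1.72 over 7 genes with 4 at least 2-fold lower, the haemoglobin genes among them; without genes listed at 0 it was -0.38 (percentile 11.5). These percentiles describe 1 pair of libraries, and no list was tested against the spread between embryo samples.

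The Hippo-YAP components and the somatic YAP-TEAD targets lay inside the range of random lists at the 4-cell stage. The 23 Hippo-YAP components had a median difference of -0.15 (percentile 13.4), with 5 at least 2-fold lower and 3 higher. Besides Yap1, the kinase gene Lats2 was at 0.205 FPKM in the YAP-null and 3.87 FPKM in the wild-type library and Amot, an angiomotin gene, at 0.270 and 3.22 FPKM, while Limd1 (19.7 and 6.80 FPKM) and Stk3 (4.75 and 1.42 FPKM) were higher. The 14 YAP-TEAD targets had a median of 0.22 (percentile 62.3), with 3 at least 2-fold lower and 4 higher. Cyr61, a common readout of YAP activity in somatic cells, was at 0.209 and 5.28 FPKM, and F3 and Tgfb2 were higher in the YAP-null library by 1.78 and 1.56 on the log2 scale. Of the genes named as higher, Tgfb2, Stk3 and Limd1 fell from oocyte to 4-cell embryo in wild type (-4.46, -2.69 and -1.19). F3 was listed at 0 in every GV library. Random lists were not matched on this stage change, so lying inside their range does not show that these 2 lists were unchanged. The other lists inside the range were mitotic and meiotic cell cycle (median -0.04, with Wee2, an oocyte kinase gene, at 85.5 and 5.97 FPKM), glycolysis (0.14, with Ldhb at 318 and 65.0 FPKM) and DNA methylation and chromatin regulators (-0.21). So were p53 and apoptosis genes (-0.30, with Mdm4 at 170.4 and 42.9 FPKM and Bax at 32.8 and 81.1 FPKM), granulosa and cumulus cell genes (-0.26 over 3 genes, with Gja1 at 32.8 and 132.7 FPKM) and Y-linked genes (-1.25 over 3 genes, percentile 4.73, with Ddx3y listed at 0 in the YAP-null and at 2.56 FPKM in the wild-type library and Eif2s3y at 2.11 and 1.98 FPKM). Ldhb differed more between GV replicates than between the 4-cell libraries. It was at 115 and 3177 FPKM in YAP-null and at 133 and 3307 FPKM in wild-type GV libraries 1 and 2.

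**Figure D4:**
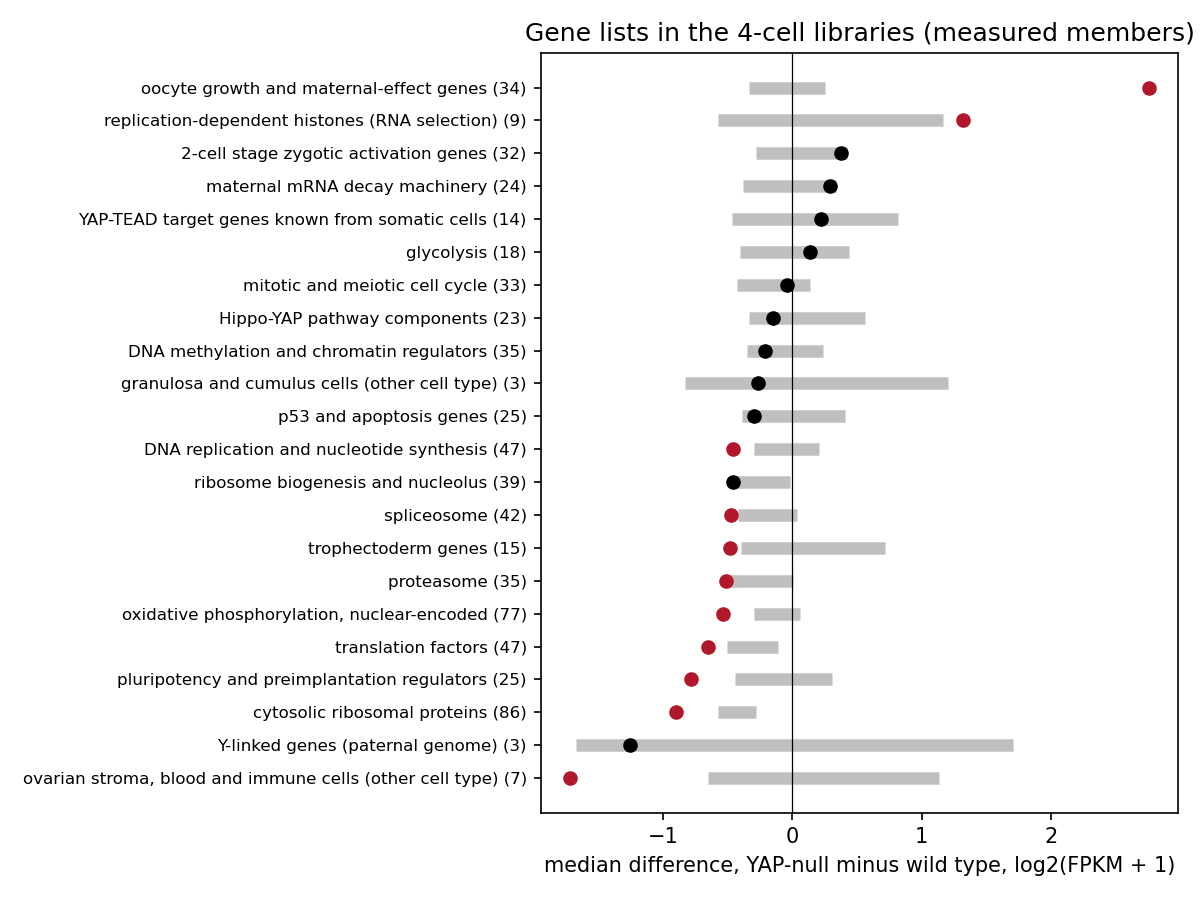
Median 4-cell difference of log2(FPKM + 1), YAP-null minus wild type, of each fixed list (points, red where outside the range), with the 2.5 to 97.5 percentile range of 10000 matched random lists as grey bars and the number of measured genes in brackets. The oocyte and maternal-effect list lies at 2.75 and the ribosomal protein list at -0.90.

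The change from GV oocyte to 4-cell embryo was described within each genotype. Metallothionein genes Mt1 and Mt2, the tetraspanin gene Cd63, the homeobox gene Obox6, Prps1 of nucleotide synthesis, the folate receptor gene Folr1, the glycine cleavage gene Gcsh, Crxos1, Trim43a and Trim43b had the largest differences upward. Mt2 was higher at the 4-cell stage by 9.14 on the log2 scale in wild type and by 9.41 in YAP-null, and Obox6 by 9.06 and 8.10. The largest differences downward were those of Plat, Gja4, Mos, Gpr1, Cpsf4l, Folr4, Gtsf1, Oas1e, Nudt7 and Tbc1d14. Mos differed by -8.25 in wild type and by -4.10 in YAP-null, Cpsf4l by -8.15 and -3.81, and Plat by -7.82 and -6.40. Of 11451 genes, 2274 were at least 4-fold higher at the 4-cell stage in wild type and 1931 in YAP-null, 1684 of them in both. The numbers at least 4-fold lower were 2169 and 1406, with 1141 in both, and 2 genes went in opposite directions. Stage differences in the genotypes, which share no library, correlated across genes at r = 0.898 and rho = 0.893 with a slope of 0.760 (YAP-null on wild type), and their median size was 1.59 in wild type and 1.29 in YAP-null. With a pseudocount of 5 FPKM the genes at least 4-fold apart came to 2231 in wild type and 1522 in YAP-null, against 4443 and 3337.

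**Figure D5:**
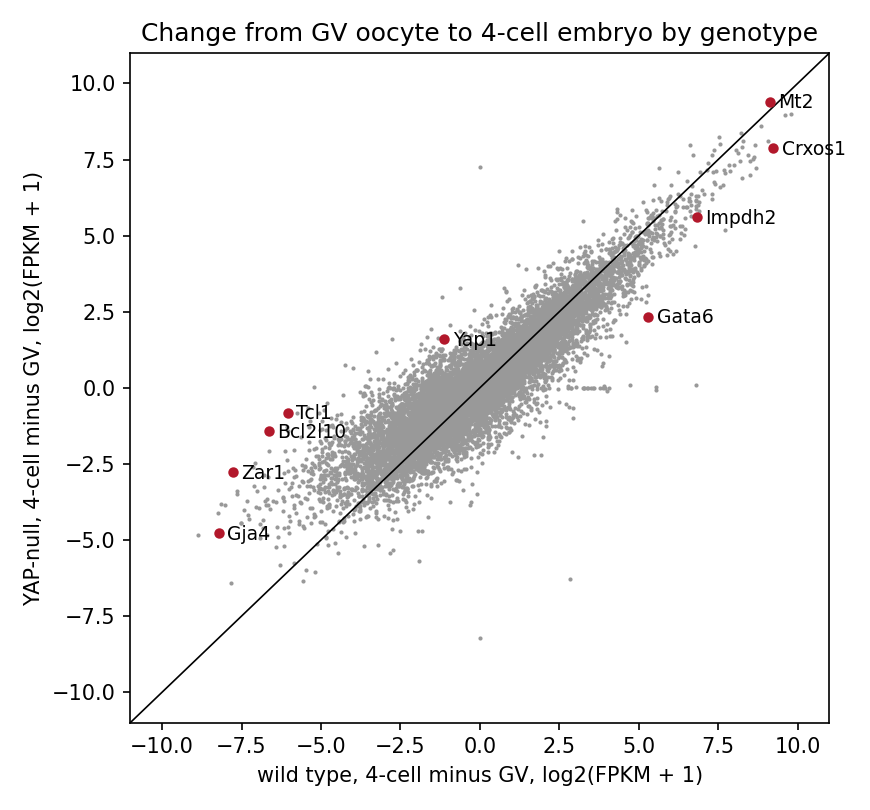
Difference of log2(FPKM + 1) between the 4-cell embryo and the mean of the GV libraries, in wild type (horizontal) and YAP-null (vertical), 1 point per gene, with the line of equal values. Bcl2l10, Tcl1 and Zar1 lie above the line on the left and Gata6 below it on the right; the slope over all genes is 0.760.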

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

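The tests of explanations in this part were chosen after the results were seen. Both YAP-null GV libraries lay on one side of both wild-type libraries in 886 genes measured at the 4-cell stage, and in 422 of them (47.6%) the 4-cell difference pointed the other way. Unrelated differences would give a similar share, and the difference between stages was not tested. Of all genes tested in GV oocytes, 10.8% were separated in this way, against 33.3% for libraries in random order. Of the 422 genes, 5 were among those named for the size of their GV or 4-cell difference. Rpl26 differed by 1.47 on the log2 scale in GV oocytes (0.56 and 2.38 within the replicate numbers) and by -7.63 in 4-cell embryos. Olfr1349 differed by -1.29 and 2.17, Tmem216 by -1.13 and 0.59, Rrs1 by -1.28 and 0.20, and Fam173b by -1.14 and 0.034, so that the 4-cell value of Fam173b is close to 0.

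Maternal decay genes were higher in the YAP-null 4-cell library (median 0.71, 1720 genes). The split between GV replicates does not account for it: over the set, the 4-cell difference and the replicate difference correlated at rho = 0.116, while the replicate differences of the 2 genotypes correlated at rho = 0.856. A uniform share of oocyte RNA, from oocytes or eggs that did not develop, remains open and cannot be told apart from slower loss of maternal transcripts. The median share was 8.54% (quartiles 2.89% and 16.6%, 839 genes). The interquartile range of observed over predicted levels was 1.15, against 0.870 between wild-type GV replicates and a bound of 1.5 times that. The test cannot decide, as that yardstick also holds the split between replicate numbers. A further candidate explanation is that the embryos labelled YAP-null were less far along the change to the 4-cell state. It is left open because the 2-cell stage genes lay at percentile 95.9, short of the 97.5 set for the lists. The genotype itself stays open as well and was not tested, since there is 1 library per genotype.

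Several genes were near 0 in the YAP-null 4-cell library although a close copy or an overlapping gene model was not. For Amd1 and Rnaset2a the difference after adding the copy was at most 0.42 on the log2 scale, against at least 4.09 before, and lay within the spread of that sum between GV replicates. This is consistent with reads being divided differently between the models, so these 2 low values may not mark a loss of transcript. For Cphx2, Plac9a, Hba-a2 and Rpl26, whose sums differed by at most 1.22 in size, the explanation stays open: the first 3 sums were 0 in at least 1 GV library, and loss of Rpl26 alone would move its sum by -0.36, inside a spread of 1.11. No biological explanation was tested for these genes.

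The GV libraries split by replicate number, with 2807 and 2438 genes at least 2-fold apart between the replicates of the YAP-null and wild-type groups. A difference in depth does not account for the split, since the libraries numbered 1, whose depths differ 3.18-fold, had 163 genes at least 2-fold apart, fewer than between replicates. A trend with transcript length correlated with the replicate difference (rho = 0.362 across genes), yet 87.4% of the genes at least 2-fold apart stayed so after its removal (1971 of 2256), so it is not the whole of the split. Collection day, animals and library batch stay open, as the labels give none of them. No biological explanation was tested.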

How the results depend on the processing

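Genes: the GV count of 0 stayed 0 under the planned pseudocounts, filters, scalings and limma settings, with 2 to 208 genes at an unadjusted p under 0.05. It was 2 to 7 without 1 library and 2 (Yap1 lower, Stk32a higher, adjusted p = 0.0131) with a replicate block, a fit that on simulated data recovered 80%, 100%, 100% and 100% of planted log2 changes of 1, 2, 4 and 6 with 36 false calls; with the block and median-ratio scaling, chosen after seeing the data, it was 2. Scaling to the same sum shifted the median GV difference to -0.14. GV lists passing: 1 at a mean of at least 5 FPKM (0 with Yap1 left out, chosen after seeing the data). Some lists passed without 1 library at the preset correlation. They did not pass with an estimated correlation (chosen after seeing the data), which could hardly pass any list with so few libraries. The preset adjusted p of lists that turned direction ranged without 1 library from 6.06e-08 to 5.71e-05 for ribosomal proteins, 0.00017 to 0.0284 for the proteasome, 0.0150 to 0.0881 for DNA replication and 5.83e-05 to 0.0120 for DNA methylation, the sign following the library left out.

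4-cell count: 1275 with a pseudocount of 5 FPKM, 1723 at a mean of at least 5 FPKM and 696 at 4-fold, each a stricter count by construction; 2960 with non-overlapping bounds (chosen after seeing the data). Maternal decay median: 0.97 and 0.66 with pseudocounts of 0.1 and 5 FPKM, 0.90 at a mean of at least 5 FPKM, 0.61 with median-ratio scaling, 0.88 with the same sum, 0.49 with quantile normalization, 0.88 without genes listed at 0 (chosen after seeing the data), 0.99 and 0.20 for sets defined on wild-type or YAP-null libraries and 1.12 at 8-fold. Zygotic median: -0.44 with median-ratio scaling and -0.041 with the same sum. Both medians kept their direction in all 17 alternatives each. Stage counts with a pseudocount of 5 FPKM were 2231 in wild type and 1522 in YAP-null. The histone list median became -0.013 with no low-value filter. The number of lists outside the range was 10 to 15, against 11. Of the values for single genes at the 4-cell stage, 74 stayed within their spread and 61 moved beyond it, the pseudocount among the causes by construction. Of those for single lists at the 4-cell stage, 174 stayed within their spread, 41 moved beyond it and 1 reversed. The cause was not tested except where the construction gives it.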

Other observations

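The tests and gene families in this part were chosen after the data were seen. Families of genes expressed in the oocyte were higher in the YAP-null 4-cell library. The 6 Tcl1 genes came to 1043 FPKM in the YAP-null and 34.1 FPKM in the wild-type library, and all 6 were at least 2-fold higher. The 6 Oas1 genes of the oocyte cluster came to 189 and 21.6 FPKM, again with 6 at least 2-fold higher. In the Nlrp4 family 4 of 5 genes, in the Nlrp9 family 3 of 3 and in the Obox family 4 of 5 were at least 2-fold higher, with medians of 2.35, 3.06 and 3.75 on the log2 scale. The Obox genes came to 1064 FPKM in the YAP-null and 615 FPKM in the wild-type library. The other Obox gene, Obox6, was at 0 to 0.279 FPKM in GV oocytes and was lower in the YAP-null 4-cell library (309 and 531 FPKM). The 6 Zscan4 genes, markers of the 2-cell embryo, had a median difference of 0.81 (58.3 and 30.9 FPKM summed), with 0 at least 2-fold higher and a percentile of 90.8, inside the range of random lists.

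Other families were lower. A group of 6 chaperone genes held Hsp90aa1, Hsp90ab1, Hspa5, Hspa8, Hspd1 and Hspe1. They came to 1863 FPKM in the YAP-null and 4530 FPKM in the wild-type library, with a median difference of -0.88 and 3 genes at least 2-fold lower. Hspa1b, a chaperone gene outside this group, was slightly higher in the YAP-null library (17.9 and 13.6 FPKM). The Klf family of transcription factors had a median of -0.51, with 4 of 11 at least 2-fold lower and 0 higher, but lay inside the range of random lists (percentile 3.06). Haemoglobin genes came to 25.9 and 93.5 FPKM, with Hba-a1 at 25.9 and 26.3 FPKM, and part of the gap is that of Hba-a2, where a different division of reads stays open. Among the remaining families looked at, the 10 Oog and Pramel genes were higher, with a median of 0.83, 4 at least 2-fold higher and 0 lower. Their percentile of 99.7 lay outside the range of random lists. The Gata family had a median of 0.26 (percentile 74.1). The sign of each family median was the same under the 3 other scalings. Prm2, a sperm protamine gene, was at 5.09 FPKM in the YAP-null 4-cell library and listed at 0 in the wild-type library, but was at 2.28 to 10.2 FPKM in GV oocytes. Mir680-2, named after its values were seen, had the highest level in the wild-type 4-cell library, at 6733 FPKM.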
